A study of Mus musculus with 20 samples.

How the data were processed

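Abdominal aortas of 20 C57BL/6 mice were analysed, 5 each of wild type with saline, wild type with AngII, Rab22a knockout with saline and Rab22a knockout with AngII. Per the labels, total RNA was depleted of ribosomal RNA before library construction. Total RNA keeps unprocessed and noncoding transcripts that selection for poly(A) tails would remove.

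The authors deposited 1 table per library of values that were read as FPKM, with 126719 transcript models in each. Of these, 110082 carry Ensembl transcript identifiers and 16637 are unannotated models without gene or coordinates. The genome build was mm10 per the submitters' processing notes, which also name limma without a version. The aligner, the transcript assembler and the counter are not given in the sources used here. Nor is it stated whether fragments or single reads were counted. The labels name no unit, and it was taken from the values and checked. Multiplied by transcript length they came in whole multiples of 1 step per library, and 98.9% to 99.0% of matched transcripts of low count lay within 0.1 read of a whole number. FPKM divides by transcript length and by a library total, so the values depend on transcript models and on all other transcripts in the library.

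Transcripts were assigned to genes with GENCODE release M21 (GRCm38, mm10). Of the Ensembl transcripts 109913 matched and 169 did not, and FPKM values were summed per gene over 42890 genes. Where gene identifiers shared a symbol, the one with the highest mean kept it. Genes with at least 1 FPKM in at least 5 libraries were tested, which left 15010. The unannotated models were left out of the gene values because they name no gene, and they held between 10.6% and 12.9% of the FPKM total of a library. The library totals implied by the values ran from about 68700000 to 77400000 reads per library. Tested genes had a median of 1404 reads per library, and 775 of 14999 with reads under their symbol had a mean under 100. Counting error was not modelled in the test on FPKM.

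All 20 libraries were fitted in 1 model with a mean per group, using limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust) on log2(FPKM + 1). The 5 comparisons were AngII against saline in each genotype, knockout against wild type under each treatment, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The labels give no batch, and replicate numbers name separate mice. The 28 gene lists, covering pathways, aortic cell types and neighbouring tissues, were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 1 FPKM, passing over predicted loci. It added up to 4 members with the smallest p of each list described, Rab22a, the AngII receptor genes and Agt, and the called neighbours of Rab22a. Single measures were compared with exact permutation tests, two-sided, over 252 arrangements of 5 against 5 libraries, for which the smallest p is 0.00794. Tests other than limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

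The alternatives were quantile normalization, scaling factors computed in the manner of TMM, limma without trend and robust, library weights, no filter, a filter at 5 FPKM, a pseudocount of 0.1, a log2 fold threshold of 1, fits of the compared groups alone, a block for the replicate number, 2 covariates for neighbouring tissue, and leaving out each library. Chosen after the data were seen were limma-voom on the whole reads recovered from FPKM, 4 tissue covariates, protein-coding genes alone, removal of the trend on transcript length and GC content, exact tests of list levels, and leaving out libraries that stood apart. The 2 covariates were the levels of the white adipocyte and skeletal muscle lists. The 4 covariates added those of B and plasma cells and of neurons and Schwann cells. The data do not show whether these cells lay in the vessel wall or beside it. The 4 covariates, called tissue covariates below, therefore need not stand for neighbouring tissue alone. Similarity of the AngII responses was the correlation across genes, set against 1000 shuffles of treatment labels within genotype. For each fitted count, 100 splits of the libraries into groups of the same sizes were drawn. On simulated data with 200 changed genes among 15010, the main test recovered 55% of changes of log2 1 and 84% of changes of log2 2, and 6.67% of its calls were false. The simulated genes varied independently of each other. Real libraries also differ in tissue content, which moves many genes together, so these shares need not hold for them.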

Results

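Rab22a is a small GTPase of endosomal membrane traffic. Angiotensin II (AngII) is a peptide hormone that constricts arteries and raises blood pressure, mainly through the type 1 receptor encoded in mice by Agtr1a and Agtr1b. Going by the title of the series, the study asked whether mice without Rab22a are protected from hypertension and vascular dysfunction caused by AngII, through the recycling of that receptor. Abdominal aortas of C57BL/6 mice were profiled by RNA sequencing of total RNA depleted of ribosomal RNA. The 20 libraries fell into 4 groups of 5 mice each, namely wild type and Rab22a knockout mice given saline or AngII (500 ng/kg/min) for 14 days. Values were available as FPKM (fragments or reads scaled to transcript length and to the library total) for 126719 transcript models per library.

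The FPKM values corresponded to about 68700000 to 77400000 reads per library, of which about 57900000 to 65500000 lay in transcripts matched to an annotated gene. Between 12504 and 14342 genes per library reached 1 FPKM. Knockout libraries held fewer transcript models above 0 than wild type libraries. Under saline the number was 80339 ± 2426 (SD, n = 5) in knockout and 86685 ± 3482 (SD, n = 5) in wild type aortas (exact permutation test, two-sided, p = 0.0238). Under AngII it was 79254 ± 3209 (SD, n = 5) and 87001 ± 3179 (SD, n = 5), with an exact permutation p of 0.0079, the smallest the design allows. The libraries also differed in the transcripts of skeletal muscle and of lymphocytes. Whether the lymphocytes lay in the vessel wall or beside it was not tested. The mean level of 23 skeletal muscle genes spanned 6.92 on the log2 scale over the 20 libraries, that of 22 B and plasma cell genes 5.499, and that of 28 T and NK cell genes 4.04.

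**Figure D1:**
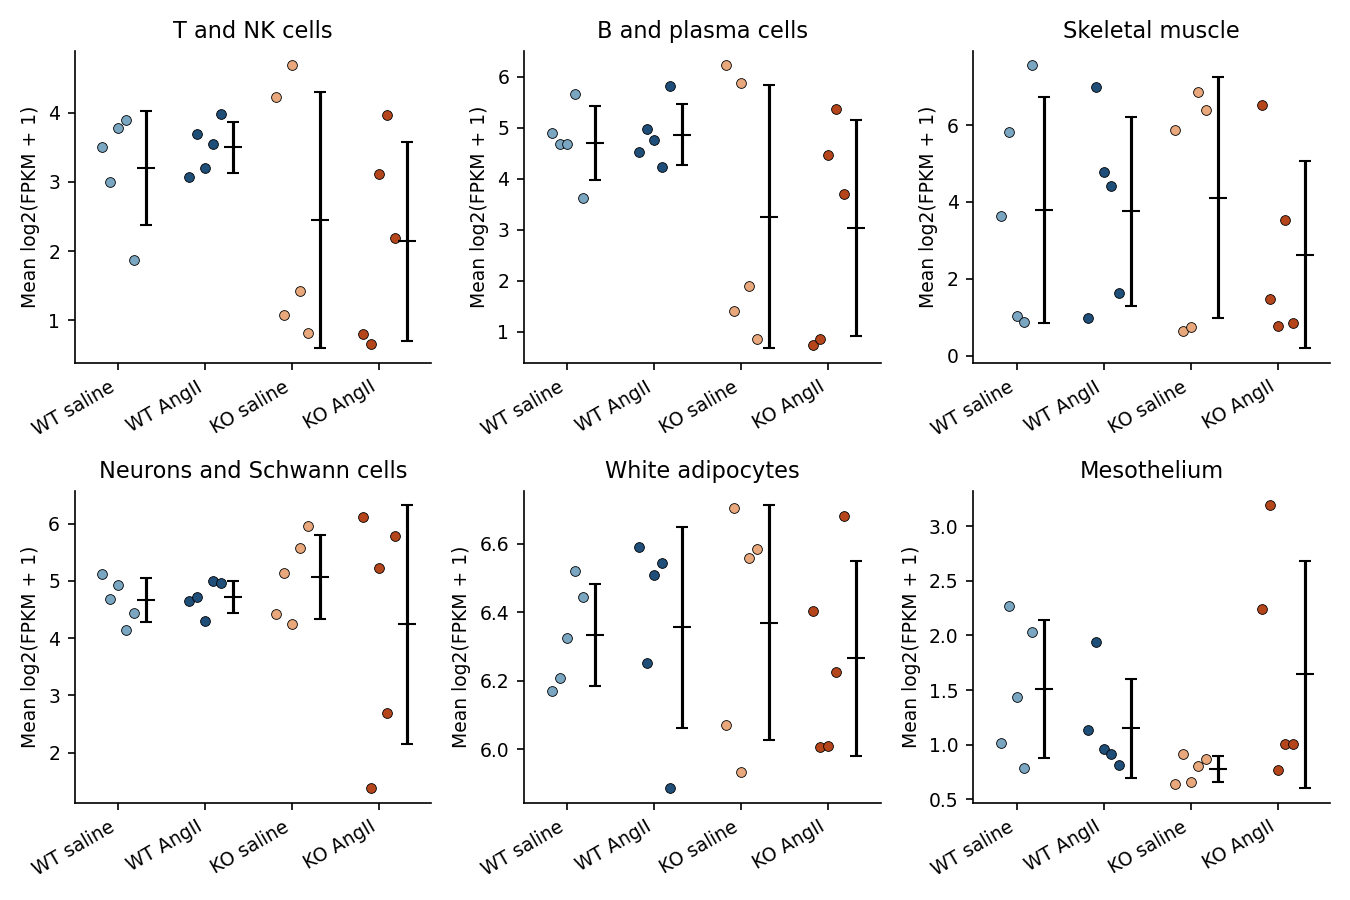
Mean log2(FPKM + 1) of the marker genes of 6 cell types in each library (points), with the group mean and SD (bars, n = 5 per group). B and plasma cell markers averaged 4.70 and 4.86 in the wild type groups, and 3.25 (SD 2.59) and 3.02 (SD 2.12) in the knockout groups, where single libraries lay between 0.73 and 6.23.

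The targeted gene was examined first. Rab22a (ENSMUSG00000027519) lies on the plus strand of chromosome 2 from 173659760 to 173707343 (mm10). Its main protein-coding transcript, ENSMUST00000029024, holds an exon 3 of 82 bases, from 173688147 to 173688228. This transcript was present in every wild type library, at 5.90 ± 2.34 FPKM (SD, n = 5) under saline and 5.96 ± 2.54 FPKM (SD, n = 5) under AngII. It was nearly absent from every knockout library, at 0.00184 ± 0.00128 and 0.00411 ± 0.00205 FPKM (SD, n = 5). The differences of log2(FPKM + 1), which the added 1 keeps small for values near 0, were -2.70 and -2.69. Each had an exact permutation p of 0.00794, the smallest possible over 252 arrangements. A second annotated transcript, ENSMUST00000142820, classed as subject to nonsense-mediated decay, lacks that exon and showed the opposite pattern. It stood at 9.38 ± 1.33 and 9.20 ± 0.60 FPKM (SD, n = 5) in knockout aortas under saline and AngII, against 2.18 ± 1.47 and 1.82 ± 1.01 FPKM (SD, n = 5) in wild type aortas, with an exact permutation p of 0.00794 for each treatment. ENSMUST00000142820 and ENSMUST00000029024 share all other exons apart from the end of the last, so their opposite differences are not independent. Summed over all transcripts of the gene, Rab22a did not differ detectably between genotypes. The sums were 9.41 ± 1.31 against 8.16 ± 3.11 FPKM (SD, n = 5) under saline (exact permutation p = 0.579), and 9.24 ± 0.60 against 7.85 ± 3.01 FPKM (SD, n = 5) under AngII (exact permutation p = 0.413). In 2 wild type libraries, saline replicate 4 and AngII replicate 2, the sum was 2.82 and 2.65 FPKM, while the other 8 lay between 7.99 and 10.4.

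**Figure D2:**
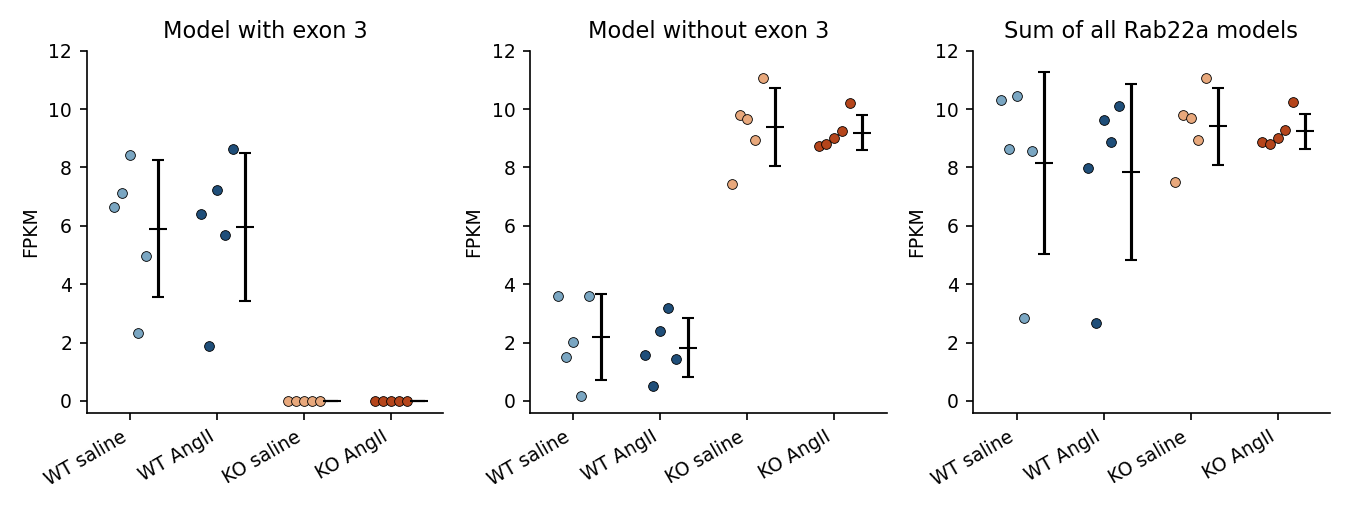
FPKM of the Rab22a transcript that holds exon 3, of the transcript that lacks it, and of the sum of all Rab22a transcripts, in each library (points) with the group mean and SD (bars, n = 5 per group). The transcript with exon 3 lies between 1.87 and 8.62 FPKM in the wild type libraries and at most at 0.00563 in the knockout libraries.

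Of the genes of the hormone and its receptors, Agtr1a, Agtr1b and Agt were tested in every comparison and passed in none. Agtr1a stood at 10.7 ± 3.63 and 9.22 ± 2.12 FPKM (SD, n = 5) in wild type aortas under saline and AngII, and at 14.8 ± 9.17 and 20.5 ± 18.4 FPKM in knockout aortas. Agtr1b lay between 0.874 and 1.20 FPKM in the group means. Agt, which encodes angiotensinogen, the precursor of the hormone, stood at 17.5 ± 5.18 and 12.9 ± 9.67 FPKM in wild type and 17.5 ± 7.13 and 10.1 ± 6.71 FPKM in knockout aortas. Agtr2, the type 2 receptor, reached at most 0.870 FPKM and was not tested, being below the filter.

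The comparison of AngII with saline in wild type mice addressed what the hormone changes in aortas with Rab22a. Extracellular matrix genes rose as a group, with 35 of 43 measured members higher under AngII and a median log2 difference of 0.48 (limma camera, adjusted p = 6.174e-10, and adjusted p = 0.974 with an estimated correlation). Among the members with the smallest p were Fn1, fibronectin, at 86.7 FPKM under saline and 177 under AngII, Timp1, an inhibitor of matrix metalloproteinases, at 5.19 and 17.5, and Thbs1, thrombospondin, at 6.19 and 13.3. Their log2 differences were 1.03 ± 0.31 (SE), 1.33 ± 0.46 and 0.89 ± 0.32. No member passed over all genes, and 0 passed when adjusted over the list alone.

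A further 5 lists were higher under AngII in wild type mice, each with an adjusted p of 0.974 with an estimated correlation. These were inflammatory cytokines and adhesion (25 of 31 members higher, median 0.23), the unfolded protein response (19 of 25, 0.12), immediate early and heat shock genes (21 of 28, 0.27), adventitial fibroblasts (13 of 18, 0.17) and macrophages and monocytes (24 of 28, 0.35). Examples were Herpud1, a component of the degradation machinery of the endoplasmic reticulum, at 18.8 ± 2.89 and 33.2 ± 9.60 FPKM, and the small heat shock gene Hspb1 at 115 ± 33.5 and 227 ± 49.9 (SD, n = 5). Medag in the fibroblast list stood at 7.88 and 11.6 FPKM, and the neutrophil gene S100a8 in the inflammatory list at 13.4 and 37.3. Adjusted over the list alone, Herpud1 and Medag passed in their lists, and no member passed over all genes. In 3 lists the members were lower, namely fatty acid metabolism (25 of 35 lower, median -0.19), brown adipocytes (15 of 18, -0.23) and mesothelium (7 of 7, -0.31). For these too the adjusted p with an estimated correlation was 0.974, and the camera adjusted p of the 8 lists ran from 0.000377 to 0.0166. Extracellular matrix, the unfolded protein response and the immediate early list kept their calls whichever of the 10 libraries was left out, and the other 6 lists did not. The immediate early mean went from 0.23 to 0.14 and the matrix mean from 0.37 to 0.31 without AngII replicate 1. That of the unfolded protein response went from 0.18 to 0.13 without saline replicate 5. Without wild type AngII replicate 5 the mean log2 difference went from 0.29 to 0.067 for macrophages and monocytes, from 0.37 to 0.22 for the inflammatory list, from -0.17 to -0.040 for fatty acid metabolism and from -0.23 to -0.063 for brown adipocytes. These 4 lists lost their calls without saline replicate 5 as well, and the last 2 also without saline replicate 2. Without saline replicate 2 the means of mesothelium and adventitial fibroblasts went from -0.36 to -0.17 and from 0.15 to 0.087. Mesothelium also lost its call without saline replicate 5 or AngII replicates 3 or 5, and fibroblasts without AngII replicate 1.

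Gene by gene, limma called 0 of 15010 genes between AngII and saline in wild type aortas. The count at an unadjusted p under 0.05 was 458, where chance would give 750, and limma-voom on whole reads also called 0. The smallest adjusted p was 0.938. Leaving out wild type saline replicate 4 or AngII replicate 3 gave 1 gene, and the 9 lists became 5 without saline replicate 5 and 4 without AngII replicate 5, the library highest in macrophage markers (5.25 against 4.00 to 4.31 in the other AngII libraries).

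The same comparison in knockout mice addressed what AngII changes without Rab22a. Extracellular matrix genes rose as a group, with 37 of 43 members higher and a median log2 difference of 0.85 (camera adjusted p = 9.57e-32, and adjusted p = 0.0475 with an estimated correlation). Of the 52 list calls in the 5 comparisons, this was the only 1 that held with an estimated correlation, and it was lost with fry (adjusted p = 0.0787). Postn, the matrix protein periostin (ENSMUSG00000027750), stood at 82.2 ± 30.9 FPKM under saline and 243 ± 77.4 under AngII (SD, n = 5), a log2 difference of 1.58 ± 0.28 (SE). Lox, which crosslinks collagen and elastin, stood at 20.7 ± 8.13 and 52.9 ± 18.4 FPKM, the connective tissue growth factor Ccn2 at 114 ± 45.4 and 402 ± 182, and the elastin gene Eln at 100.3 ± 41.0 and 334 ± 160. Adjusted over the list alone, 27 members passed, 25 of them higher, while 0 passed over all genes. The mean level of the list per library was 5.14 ± 0.43 under AngII and 4.42 ± 0.38 under saline (SD, n = 5), with an exact permutation p of 0.0397 (adjusted p = 0.444 over 28 lists). With so few arrangements a lone list could not pass this adjustment, whatever its levels. Knockout saline replicate 1 had the lowest level (3.74), and without it the mean log2 difference of the list fell from 0.72 to 0.55.

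**Figure D3:**
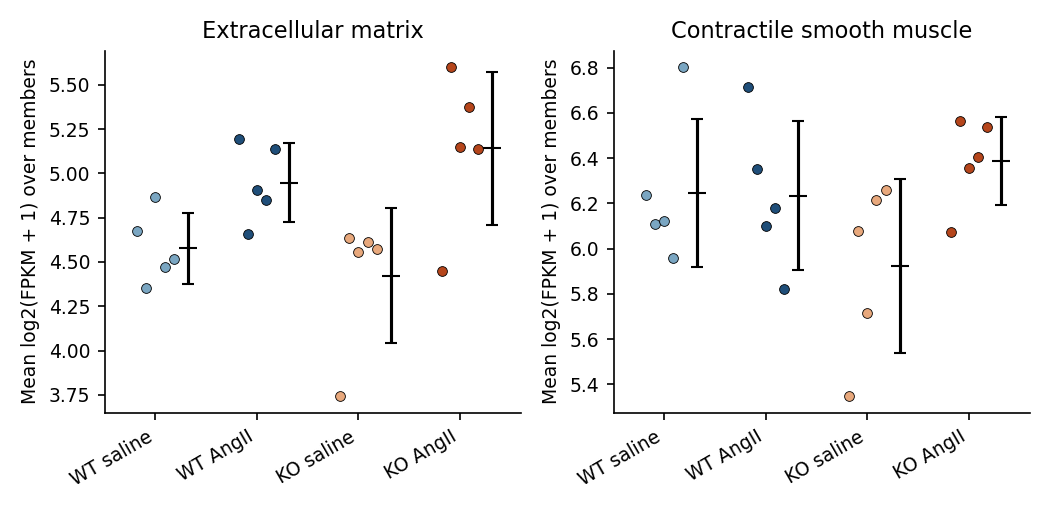
Mean log2(FPKM + 1) over the 43 extracellular matrix genes and the 24 contractile smooth muscle genes in each library (points), with the group mean and SD (bars, n = 5 per group). The matrix level averaged 4.42 under saline and 5.14 under AngII in knockout aortas, and 4.58 and 4.95 in wild type aortas.

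Contractile smooth muscle genes were higher under AngII in knockout aortas as well (22 of 24 members, median 0.47, adjusted p = 0.209 with an estimated correlation). The calponin gene Cnn1 stood at 93.2 ± 33.6 and 177 ± 60.1 FPKM and the integrin subunit gene Itga8 at 32.5 ± 12.2 and 58.7 ± 17.7 (SD, n = 5). Also higher were oxidative phosphorylation (31 of 35, median 0.23), fatty acid metabolism (27 of 35, 0.24), adventitial fibroblasts (13 of 18, 0.08), brown adipocytes (15 of 18, 0.52), mesothelium (7 of 7, 0.76) and 4 sex-linked transcripts (2 of 4, 0.17). With an estimated correlation the adjusted p of these 6 lists ran from 0.209 to 0.820. Without knockout saline replicate 3 the mean log2 difference went from 0.19 to 0.0040 for oxidative phosphorylation, from 0.20 to -0.029 for fatty acid metabolism and from 0.48 to 0.18 for brown adipocytes, and these 3 lists lost their calls without AngII replicate 2 as well. Without saline replicate 1 the fibroblast mean went from 0.11 to -0.011, and without saline replicate 5 the sex-linked mean from 0.16 to 0.021. The fibroblast call was also lost without AngII replicate 5, and the sex-linked call when any of 6 libraries was left out. Extracellular matrix, contractile smooth muscle and mesothelium kept their calls whichever of the 10 libraries was left out, although the mesothelium mean fell from 0.87 to 0.48 without AngII replicate 2. Within oxidative phosphorylation, the ATP synthase genes Atp5d (log2 difference -1.01 ± 0.55) and Atp5g3 (-0.45 ± 0.26) went the other way.

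Lower under AngII in knockout aortas were the interferon response (29 of 32, median -0.34), with Isg15 at 17.3 ± 17.3 and 7.55 ± 2.31 FPKM (SD, n = 5), and the cell cycle (32 of 33, -0.39), where Anln was the exception (3.16 ± 1.23 and 6.69 ± 2.89 FPKM). So were skeletal muscle (19 of 23, median -1.50), neurons and Schwann cells (22 of 25, -0.92) and the adrenal cortex, kidney and liver list (7 of 8, -0.67). In that list albumin, a liver transcript, stood at 76.8 ± 79.7 FPKM under saline and 7.29 ± 4.68 under AngII. With an estimated correlation the adjusted p of these 5 lists ran from 0.529 to 0.941, and each depended on single libraries. Without knockout AngII replicate 2, where the nerve list stood at 1.38, its mean log2 difference went from -0.83 to -0.11, and its call was also lost without AngII replicate 4 or saline replicates 2, 4 or 5. Without saline replicate 1 the interferon mean went from -0.36 to -0.10 with its call lost, and the cell cycle mean from -0.33 to 0.11, which turned it higher. The cell cycle call was also lost without saline replicate 3 or AngII replicates 1 or 5. Without saline replicate 4 the skeletal muscle mean went from -1.48 to -0.79 and that of the adrenal, kidney and liver list from -0.78 to -0.55, and each of these lists lost its call when any of 5 libraries was left out. For the 12 lists other than extracellular matrix the camera adjusted p ran from 1.008e-13 to 0.0381 and the adjusted p with an estimated correlation from 0.209 to 0.941. Adjusted over the list alone, 0 of their members passed. Limma called 0 of 15010 genes, with 595 at an unadjusted p under 0.05 and 0 by limma-voom. Leaving out knockout AngII replicate 1 gave 4 genes and leaving out AngII replicate 4 gave 1, and the 13 lists became 8 without AngII replicate 5.

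Knockout was compared with wild type under saline to find what loss of Rab22a changes before any AngII. Limma called 2 of 15010 genes, both lower in knockout, and 1106 genes had an unadjusted p under 0.05. They are named here although their values had been seen when they were chosen. Gm10800 (ENSMUSG00000075014, chromosome 2 from 98666547 to 98667301) stood at 54.0 ± 38.6 FPKM in wild type and 0.127 ± 0.140 FPKM in knockout aortas (SD, n = 5). Its log2 difference was -5.30 ± 0.50 (SE, adjusted p = 4.465e-05), and over both treatments its lowest wild type value was 7.92 FPKM and its highest knockout value 0.743 FPKM. The long noncoding RNA 6720427I07Rik (ENSMUSG00000097375, chromosome 13 from 48532905 to 48546500) stood at 2.96 ± 0.28 and 1.37 ± 0.41 FPKM (SD, n = 5), a log2 difference of -0.75 ± 0.12 (adjusted p = 0.0423). The same 2 genes were called under AngII, with log2 differences of -3.69 and -0.54 (adjusted p = 0.00464 and 0.0310).

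Under saline, 7 lists were lower and 4 higher in knockout aortas, and with an estimated correlation their adjusted p ran from 0.614 to 0.918. Oxidative phosphorylation genes were lower in 33 of 35 members (median -0.44), with the cytochrome c oxidase subunit Cox5b at 260 ± 80.9 FPKM in wild type and 151 ± 52.4 in knockout (SD, n = 5). Contractile smooth muscle genes were lower in 20 of 24 (-0.41), with smooth muscle actin, Acta2, at 1716 ± 336 and 1108 ± 379 FPKM. Fatty acid metabolism (27 of 35 lower, -0.40) and brown adipocytes (17 of 18, -0.72) were lower, with Acadm, an enzyme of fatty acid oxidation, at 551 ± 120 and 355 ± 149 FPKM. Lymphocyte markers were lower on average, with 24 of 28 T and NK cell genes (-0.85) and 20 of 22 B and plasma cell genes (-1.47), and the immunoglobulin joining chain gene Jchain stood at 149 ± 93.3 and 28.0 ± 42.8 FPKM. The knockout group was split, however. Knockout replicates 1 and 3 lay above every wild type saline library in both lists (B and plasma cells 6.23 and 5.88 against at most 5.65, T and NK cells 4.23 and 4.69 against at most 3.89), and the other 3 lay below all of them, so the list levels did not differ detectably (exact permutation p = 0.23 and 0.437). Cd79a stood at 59.6 ± 29.1 and 46.2 ± 59.7 FPKM, highest in those 2 knockout libraries. The immunoglobulin light chain gene Igkc, named after its values had been seen, had the higher mean in knockout (734 ± 353 and 1627 ± 2345). Mesothelial markers were lower in 7 of 7 (-0.65). Higher in knockout were the interferon response (22 of 32, median 0.22), cholesterol synthesis (16 of 19, 0.34), the circadian clock (14 of 17, 0.10) and neurons and Schwann cells (22 of 25, 0.42). Ifit3, an interferon-induced gene, stood at 6.85 ± 1.82 and 15.6 ± 11.04 FPKM, and Cry2, a clock repressor, at 12.7 ± 1.25 and 16.0 ± 2.43. The camera adjusted p of the 11 lists ran from 1.251e-08 to 0.0174. Adjusted over the list alone, 0 members of these 11 lists passed, as over all genes. Oxidative phosphorylation, cholesterol synthesis, B and plasma cells and mesothelium kept their calls whichever of the 10 libraries was left out, and the other 7 lists did not. Without knockout saline replicate 1, the library highest in the interferon list (4.53), the interferon mean went from 0.19 to -0.068, and that of contractile smooth muscle from -0.32 to -0.18. Knockout replicate 3 (4.05) also lay above every wild type library in the interferon list (at most 3.73), while knockout replicates 2, 4 and 5 stood at 2.93, 3.13 and 2.90. Without knockout replicate 3 the mean of fatty acid metabolism went from -0.28 to -0.054 and that of brown adipocytes from -0.64 to -0.34. Without knockout replicate 5 the mean of T and NK cells went from -0.76 to -0.35 and that of neurons and Schwann cells from 0.40 to 0.18, and without knockout replicate 2 that of the circadian clock from 0.15 to 0.0997. Each of these 7 lists lost its call there. Among the lists that kept theirs, oxidative phosphorylation went from -0.42 to -0.23 without knockout replicate 3 and B and plasma cells from -1.45 to -0.85 without knockout replicate 5. Cholesterol synthesis went from 0.34 to 0.22 without wild type replicate 3 and mesothelium from -0.73 to -0.54 without wild type replicate 2.

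The count of 2 genes became 1 when any single one of wild type saline replicates 1, 2, 4 and 5 or knockout saline replicates 2, 4 and 5 was left out, and 4 without knockout saline replicate 3. It was 2 without wild type saline replicate 3 or knockout saline replicate 1, but each time 1 was a different gene, higher in knockout. Library weights gave 1195 genes, 161 higher and 1034 lower, and testing with no filter gave 20, all lower. Limma-voom on whole reads called 148 genes, 7 higher and 141 lower. With 4 covariates for neighbouring tissue, chosen after the data had been seen, T and NK cell genes were higher in knockout, with a mean of 0.21. The level of the B and plasma cell list was 1 of the 4, so this value sets 1 lymphocyte list against another.

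The comparison of genotypes under AngII addressed how aortas with and without Rab22a differ in the treated state. Limma called 275 of 15010 genes, 59 higher and 216 lower in knockout, with 2593 at an unadjusted p under 0.05. Among the genes higher in knockout were Fyco1 (ENSMUSG00000025241, chromosome 9 from 123789500 to 123851899), an adaptor of late endosomes and autophagosomes, at 6.60 ± 4.29 FPKM in wild type and 22.1 ± 4.61 in knockout (SD, n = 5), and the matricellular gene Ccn1 at 31.2 ± 23.1 and 102 ± 50.4. Slc6a6, the taurine transporter, stood at 9.07 ± 2.91 and 30.1 ± 9.90 FPKM, and Arhgap35, a GTPase-activating protein, at 5.94 ± 3.34 and 14.7 ± 2.25. Their log2 differences were 1.83 ± 0.33 (SE), 1.71 ± 0.43, 1.62 ± 0.34 and 1.34 ± 0.28. Rmnd5a (1.10), Acadsb (1.08) and Hmbox1 (0.98) were also among the largest increases.

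Among the genes lower in knockout, with predicted loci such as Gm10800 (-3.69) passed over, the immunoglobulin heavy chain gene Ighg1 had the largest difference (74.2 ± 52.4 FPKM in wild type and 3.86 ± 8.19 in knockout, log2 -4.56 ± 1.13), followed by the calcium-binding protein gene S100a13 (23.2 ± 13.0 and 1.05 ± 2.34, -3.91) and the ribosomal protein gene Rps27a (156 ± 177 and 8.50 ± 8.50, -3.46). The SD exceeded the mean for Rps27a in wild type and for Ighg1 and S100a13 in knockout aortas. Loss of their reads to unannotated models, which the gene values leave out, was not tested. The splicing factor gene Srsf9 stood at 26.7 ± 3.597 and 6.71 ± 0.989 FPKM (SD, n = 5), the noncoding Snhg20 at 34.0 ± 10.7 and 8.87 ± 2.44, and the small nucleolar RNA Snora24 at 6.73 ± 1.17 and 1.56 ± 0.732. The stress-inducible Gadd45g (58.3 ± 22.9 and 20.8 ± 5.78) and the ribosomal protein gene Rps19 (519 ± 107 and 216 ± 70.4) completed the set. By class, 227 of the 275 genes were protein coding, and 34 were processed pseudogenes, all 34 lower. Of all 656 tested processed pseudogenes 517 were lower, with a median log2 difference of -0.26. Of 178 tested genes whose symbols begin with Rps or Rpl, 11 were called, all 11 lower. The median log2 difference of the 178 was -0.59, and it was -0.37 after quantile normalization and -0.50 with scaling factors, against -0.10, 0.03 and -0.03 for all genes. Without rescaling, the lowest quintile of transcript length had a median of -0.32 and the highest quintile of 0.14. Neither the ribosomal protein genes nor the pseudogenes were set against genes of like length, so a share due to length is not separated.

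The 59 higher genes had a median transcript length of 5465 bases and the 216 lower genes of 1052 bases, against 2473 bases for all tested genes. Across genes, which are not independent replicates, the log2 difference and transcript length had a Spearman correlation of 0.44. The slope of log2 value on the log2 of length per library was 0.078 ± 0.062 in knockout and -0.093 ± 0.061 in wild type aortas under AngII (SD, n = 5, exact permutation p = 0.0159). The slope on GC content was lower in knockout than in wild type aortas under AngII (exact permutation p = 0.0079, the smallest possible). Quantile normalization, which moves the median of all genes by more than 0.1, gave 250 higher and 124 lower genes, and scaling factors gave 183 higher and 132 lower. Whole reads with limma-voom gave 306 higher and 292 lower. Removing the trend on length and GC content from each library, a step chosen after the data had been seen, left 14 genes, 7 in each direction and 12 of them among the 275.

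**Figure D4:**
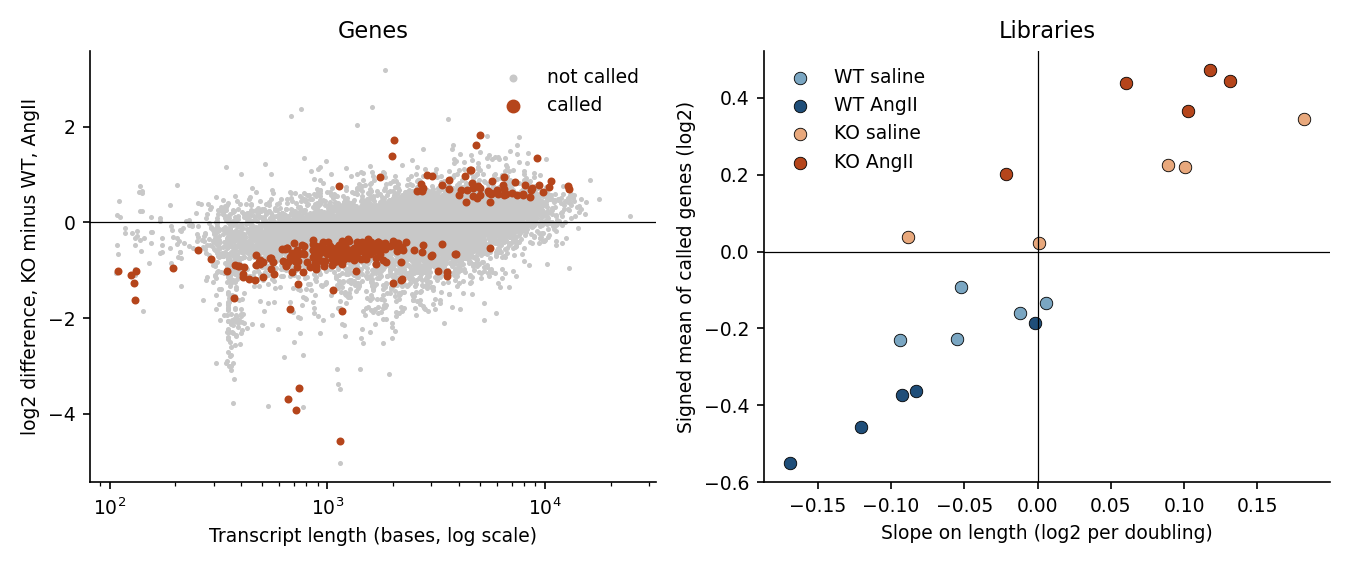
Left, log2 difference between knockout and wild type under AngII against transcript length (log axis) for each tested gene, with the 275 called genes in red. Right, for each library, the mean of the called genes after centring each gene and giving it the sign of its difference, against the slope of log2 value on the log2 of length. Saline knockout libraries average 0.17 and saline wild type libraries -0.17.

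By list, 7 were called under AngII, each with an adjusted p of 0.948 with an estimated correlation. T and NK cell genes (28 of 28 lower, median -1.54) and B and plasma cell genes (22 of 22, -1.75) were lower in knockout aortas under AngII, with Cd79a, a component of the B cell receptor, at 65.4 ± 19.2 FPKM in wild type and 20.3 ± 21.7 in knockout (SD, n = 5). The knockout group was split here too. Replicates 3 and 4 lay within the wild type range in both lists (T and NK cells 3.11 and 3.97 against 3.07 to 3.99, B and plasma cells 4.47 and 5.37 against 4.24 to 5.82), the other 3 lay below it, and the exact permutation p of the list levels was 0.0952 and 0.119. Macrophage and monocyte genes were lower in 24 of 28 (-0.68). Of these Gpnmb passed over all genes and adjusted over the list alone, at 22.01 ± 4.29 and 10.1 ± 3.87 FPKM. The unfolded protein response was lower in 21 of 25 (-0.29). There Herpud1 (33.2 ± 9.60 and 17.7 ± 2.58 FPKM) and the stress-induced transcription factor gene Ddit3 (31.05 ± 3.23 and 20.999 ± 1.39) fell, and the chaperone gene Hyou1 (10.5 ± 3.03 and 19.7 ± 2.11) rose. These 3 passed over all genes and 4 passed adjusted over the list alone. Extracellular matrix (29 of 43 higher, median 0.17), contractile smooth muscle (16 of 24, 0.14) and mesothelium (7 of 7, 0.58) were higher, and Ccn1 in the matrix list passed over all genes and adjusted over the list alone. No member of the lymphocyte or mesothelium lists passed either way. Over the 7 lists 6 members passed over all genes, not all of them named here. The camera adjusted p of the 7 lists ran from 0.00124 to 0.0359. Of these, T and NK cells alone kept the call whichever of the 10 libraries was left out. Without knockout AngII replicate 2 the mean log2 difference went from 0.49 to 0.10 for mesothelium and from 0.19 to 0.079 for extracellular matrix. Without wild type AngII replicate 5 it went from 0.15 to 0.050 for contractile smooth muscle, from -0.59 to -0.37 for macrophages and monocytes and from -0.31 to -0.26 for the unfolded protein response, and without knockout replicate 1 from -1.84 to -1.27 for B and plasma cells. Each of these lost its call there. Rab and endocytic recycling genes, the family of the targeted gene, were not called as a list (median -0.06, mean -0.01, camera direction up, adjusted p = 0.282). The early endosome tether Eea1 passed over all genes (7.51 ± 1.24 FPKM in wild type and 11.7 ± 1.56 in knockout, log2 0.58 ± 0.14, adjusted p = 0.0454). Adjusted over the list alone, Rab5a (26.1 ± 1.70 and 36.3 ± 4.37 FPKM) and Rab4b (31.4 ± 4.34 and 19.7 ± 4.80) passed as well.

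The count of 275 genes depended on single libraries. It was 11, 14, 484 and 38 without wild type AngII replicates 1, 2, 3 and 4, and 177 without replicate 5. It was 51, 28, 9 and 64 without knockout AngII replicates 1, 2, 3 and 5, and 377 without replicate 4. A fit of these 2 groups alone called 1 gene. The 7 lists became 4 without wild type AngII replicate 5 and 3 without knockout AngII replicate 1. With 4 covariates for neighbouring tissue, chosen after the data had been seen, extracellular matrix (mean -0.077) and mesothelium (-0.15) were lower instead of higher in knockout.

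The interaction compared the AngII response between genotypes, which is the test of whether loss of Rab22a altered it. By list, 12 were called with the preset correlation, and with an estimated correlation their adjusted p ran from 0.688 to 0.812. Response differences of lists were positive, meaning a higher response in knockout, for extracellular matrix (33 of 43 members, median 0.26), contractile smooth muscle (22 of 24, 0.48), oxidative phosphorylation (33 of 35, 0.30), fatty acid metabolism (27 of 35, 0.41), brown adipocytes (17 of 18, 0.74) and mesothelium (7 of 7, 1.03). Postn had an interaction of 1.10 ± 0.40 (SE), Lox of 1.12 ± 0.41 and Itga8 of 1.36 ± 0.44. They were negative for inflammatory cytokines and adhesion (26 of 31, median -0.35), the interferon response (28 of 32, -0.36), the cell cycle (31 of 33, -0.52), cholesterol synthesis (17 of 19, -0.27), the unfolded protein response (20 of 25, -0.36) and neurons and Schwann cells (22 of 25, -0.95). Herpud1 had an interaction of -0.86 ± 0.26 (SE) and S100a8 of -2.02 ± 0.90, which became -1.20 without knockout saline replicate 3 (317 FPKM, the other 4 of that group 10.98 to 24.4). The camera adjusted p of the 12 lists ran from 4.962e-08 to 0.0373. Adjusted over the list alone, 0 members of these lists passed. Limma called 0 of 15010 genes, with 501 at an unadjusted p under 0.05 and 0 by limma-voom. Extracellular matrix, contractile smooth muscle, the unfolded protein response, brown adipocytes and mesothelium kept their calls whichever of the 20 libraries was left out. Without knockout AngII replicate 2 the mean interaction of neurons and Schwann cells went from -0.89 to -0.17. Without knockout saline replicate 1 that of the cell cycle went from -0.47 to -0.029 and that of the interferon response from -0.36 to -0.10. Without knockout saline replicate 3 that of the inflammatory list went from -0.52 to -0.18, of oxidative phosphorylation from 0.23 to 0.046 and of fatty acid metabolism from 0.37 to 0.15, and without wild type saline replicate 3 that of cholesterol synthesis from -0.34 to -0.22. Each of these 7 lists lost its call there, and the 12 lists became 8 without wild type or knockout AngII replicate 5. Among the lists that kept theirs, the matrix mean went from 0.35 to 0.18 without knockout saline replicate 1. That of brown adipocytes went from 0.71 to 0.41 without knockout saline replicate 3, and that of mesothelium from 1.22 to 0.83 without knockout AngII replicate 2.

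Of the 28 lists, 7 were called in no comparison. Their smallest camera adjusted p was 0.110 for Rab and endocytic recycling, 0.276 for endothelial cells, 0.287 for erythrocytes, 0.209 for oxidative stress enzymes, 0.209 for the renin-angiotensin system and receptor signalling, 0.1525 for vasoactive receptors and channels and 0.868 for white adipocytes.

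Across the 15010 genes, the log2 responses to AngII in wild type and in knockout aortas had a Pearson r of -0.06 and a Spearman correlation of -0.10, and 45.1% of genes had the same sign. Shuffling the treatment labels within each genotype gave a correlation as high in 642 of 1000 shuffles, so the similarity did not differ from that of shuffled labels. Leave-one-out values ran from -0.14 to 0.02, the latter without knockout saline replicate 3.

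Genes near Rab22a were examined because a targeted locus can carry flanking sequence of another strain. Within 5 Mb, 3 of 67 tested genes were called between genotypes under AngII (4.48%), against 272 of 14942 elsewhere (1.82%, Fisher's exact test, two-sided, p = 0.125). Among them were Zfp971, a zinc finger gene (3.92 ± 0.892 FPKM in wild type and 7.34 ± 1.40 in knockout under AngII), and Nelfcd, a subunit of the negative elongation factor (24.9 ± 2.09 and 17.2 ± 2.77).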

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

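The counts over other splits of the libraries, the tests with 4 tissue covariates, the test of vessel wall share and both tests on the low Rab22a libraries were chosen after the results they bear on had been seen, and removal of the length and GC trend was an alternative added after the data had been seen.

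Knockout and wild type aortas differed in 275 genes under AngII. Of 100 splits 1, the real one, gave as many and the highest other gave 2, so a chance division of the libraries is unlikely to give this count. The splits do not test single genes. The count was 1 in a fit of these 2 groups alone, 9 without knockout AngII replicate 3 and 14 with the length and GC trend removed. Removing the trend on length and GC content from each library kept 51.9% of the median absolute log2 difference (0.667 with a median SE of 0.144 before, 0.346 with 0.134 after), and 12 of the genes were still called, the rest being lost because the differences shrank. With 4 covariates for neighbouring tissue 88.4% was kept (0.589, median SE 0.150) and 41 genes were still called. With the 2 planned covariates all 275 were among 614 called, but those 2 hold no lymphocyte or nerve list. Neighbouring tissue as a source is therefore not decided, since most of the difference was kept and most calls were lost. The animal numbers of saline mice run low in wild type and high in knockout with 1 exception in each, and both of these 2 mice lay nearer to their own genotype, as the planned criterion against a cohort asked, but 1 by over 1 SD, a margin set after the values had been seen (the wild type mouse at -0.134, the knockout mouse at 0.037 between group means of 0.17 and -0.17). The slope on length was -0.088 in this knockout mouse and 0.006 in this wild type mouse, between saline group means of 0.057 and -0.042. It was -0.083 in wild type AngII replicate 5, also numbered among the knockouts. The slope differed between genotypes under AngII, less clearly under saline (exact permutation p = 0.0159 and 0.0873). A length or GC bias between libraries, the cohort of animals and the genotype itself therefore cannot be told apart, because so few exceptional mice cannot separate them.

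Extracellular matrix genes were higher under AngII in knockout aortas, by a mean log2 of 0.72. With 4 tissue covariates the mean was 0.51 and the list stayed past the threshold (camera with the preset correlation, adjusted p = 3.716e-13). Neighbouring tissue is not excluded by this, because the covariates hold neither mesothelium nor brown adipocytes. Knockout AngII replicate 2 had the highest level of all libraries in both of those lists (3.20 and 5.60) and in the matrix list (5.60). With the preset correlation 55 of 100 splits gave as many called lists as the 13 seen, so chance cannot be excluded for the count of lists. Taking the contractile smooth muscle level from the matrix level in each library left a difference of 0.26 of the 0.72 (exact permutation p = 0.143). A larger share of vessel wall in the AngII samples may therefore account for part of the rise, and an effect of AngII on matrix genes stays open. In wild type aortas the same step left 0.38 of 0.37 (exact permutation p = 0.167).

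The sum of Rab22a transcripts was far from the other wild type libraries in saline replicate 4 (2.82 FPKM, the others 8.57 to 10.4) and AngII replicate 2 (2.65 FPKM, the others 7.99 to 10.1). Both held the transcript with exon 3 at 1.87 FPKM or more, against at most 0.00563 in knockout libraries, which argues against mislabelled knockout samples. In both, 4 unannotated models stood above 1 FPKM and below 0.1 FPKM in the other 18 libraries, and reads of Rab22a may have been assigned to 1 of them. Random pairs of libraries held a median of 2 such models, with a highest of 9, and the models have no coordinates, so this cannot be told apart from chance. No biological explanation was tested.

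Of 122 groups of 5 libraries examined, 8 held a library far from the rest, where chance gives about 6.1. Beside the 2 Rab22a sums these were the matrix list in knockout saline replicate 1 (mean log2 level 3.74, the others 4.55 to 4.64) and the fibroblast list in the same library (5.25, the others 5.78 to 5.97). The endothelial list stood at 5.05 in knockout saline replicate 3 (the others 4.54 to 4.68). Wild type AngII replicate 5 was high in the cell cycle list (2.97, the others 1.57 to 1.84) and in macrophages and monocytes (5.25, the others 4.00 to 4.31). The mesothelium list stood at 1.94 in wild type AngII replicate 2 (the others 0.81 to 1.13).

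The AngII response differed between knockout and wild type for 12 lists by the interaction test with a preset correlation, and for 0 with an estimated correlation. The mean response differences were 0.35 for extracellular matrix, 0.48 for contractile smooth muscle, 0.23 for oxidative phosphorylation, 0.37 for fatty acid metabolism, 0.71 for brown adipocytes and 1.22 for mesothelium. They were -0.52 for inflammatory cytokines and adhesion, -0.36 for the interferon response, -0.47 for the cell cycle, -0.34 for cholesterol synthesis, -0.31 for the unfolded protein response and -0.89 for neurons and Schwann cells. Of these 12, 7 lost the call when some single library was left out, and without knockout AngII replicate 2 the mean for neurons and Schwann cells was -0.17. Without knockout saline replicate 1 the means for the cell cycle and the interferon response were -0.029 and -0.10. Without knockout saline replicate 3 those for the inflammatory list, oxidative phosphorylation and fatty acid metabolism were -0.18, 0.046 and 0.15, and without wild type saline replicate 3 that for cholesterol synthesis was -0.22. Among the lists that kept the call, extracellular matrix fell to 0.18 without knockout saline replicate 1 and brown adipocytes to 0.41 without knockout saline replicate 3. As many lists were called in 40 of 100 splits, with a highest of 21, so chance cannot be excluded.

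Among the unannotated transcript models, which no comparison of genes uses, 58 of 8760 tested were called between genotypes under saline (2 higher and 56 lower in knockout) and 43 under AngII (4 higher and 39 lower), 29 of them in both. Between AngII and saline limma called 0 in wild type and 0 in knockout aortas, with 411 and 396 at an unadjusted p under 0.05.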

How the results depend on the processing

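Limma-voom, 4 tissue covariates, protein-coding genes alone, removal of the length and GC trend, exact tests of list levels and the settings without the low Rab22a or nerve-poor libraries were chosen after seeing the data, and the cause of the changes below was not tested except where fewer genes or libraries entered. For knockout against wild type under AngII (275 genes) the count was 1913 with library weights, 37 with a log2 fold threshold of 1, 1 with these 2 groups alone, 70 with the replicate block, 614 with 2 and 72 with 4 tissue covariates, 598 by limma-voom, 14 with the length and GC trend removed, 4 without the 2 wild type libraries low in Rab22a and 28 without knockout AngII replicate 2, and 9 to 484 leaving out 1 library. Under saline (2 genes) it was 1195 with library weights, 20 with no filter, 148 by limma-voom and 9 with 4 covariates. It was 1 with quantile normalization, the stricter filter, the fold threshold, 2 groups alone, the block, 2 covariates, coding genes alone and both sets of libraries left out, and 1 to 4 leaving out 1 library. AngII against saline (0 genes) gave 2 in wild type and 2 in knockout with library weights, 11 in wild type with no filter, and 0 to 1 and 0 to 4 leaving out 1 library. The interaction (0 genes) gave 1 with no filter and 0 in every library left out.

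Called lists were 0 with fry in all 5 comparisons, 0 with exact tests of list levels in the 4 run, and 0 with an estimated correlation except 1 for AngII in knockout. The count from the exact tests decides little. Their smallest p is 0.0079, so a lone list could not pass after adjustment over 28 lists. Under AngII the 7 lists between genotypes became 4 with the stricter filter, 4 with a pseudocount of 0.1, 11 with 2 and 2 with 4 covariates, and 3 to 10 leaving out 1 library. The 9 lists in wild type became 3 with no filter, and 4 to 13 leaving out 1 library. The 12 of the interaction became 7 with the stricter filter and 8 to 15, the 13 in knockout 8 to 13 and the 11 under saline 9 to 14 leaving out 1 library. Directions reversed for the sex-linked list in knockout with the stricter filter (-0.11), with 4 covariates, B and plasma cells among them, for T and NK cells under saline (0.21), and for matrix (-0.077) and mesothelium (-0.15) between genotypes under AngII. Leaving out 1 library, the cell cycle ran from -0.55 to 0.11 in knockout and from -0.69 to -0.029 in the interaction, the highest of each without knockout saline replicate 1. Fatty acid metabolism ran from -0.029 to 0.37 in knockout and from -0.45 to -0.054 under saline, and both turned against the other genes without knockout saline replicate 3.

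Leaving out 1 library, the exon 3 transcripts of Rab22a differed by -2.91 to -2.57 under saline and -2.93 to -2.53 under AngII, the sum by -0.02 to 0.38 and 0.02 to 0.42, and the response similarity ran from -0.14 to 0.02. The similarity over genes called in wild type had no value, as 0 were called. Replicate numbers did not pair the mice (mean correlation of same-number libraries -0.03, and 3 of 20 libraries matched their own number best). Of the list values 1050 kept direction and side of the threshold and 343 lost the call. Of the values of named genes 7569 kept both, 93 that were called neither way changed sign and 41 gained a call, while 271 of 542 values of the 21 called named genes lost the call. With 5 mice per group, changes of log2 1 were recovered in 55% of simulated genes, which varied independently of each other, so the share need not hold for the real libraries.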

Other observations

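The test of genes under saline, the test of mt-Nd5 and the shuffles of treatment labels were written before their results were seen, and the counts over other splits were chosen after.

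The values in all 4 groups are given for 5 of the genes called between genotypes under AngII, picked after their values had been seen. Their AngII responses were not shown to differ between genotypes, since limma called 0 genes for the interaction (smallest adjusted p 0.995, 501 at an unadjusted p under 0.05, and 0 by limma-voom). Of the 275 genes called between genotypes under AngII, 13 had a mean under 100 reads. With the length and GC trend removed, 12 of the 275 were still called. Fyco1 stood at 19.2 ± 1.18 FPKM in wild type saline, 19.95 ± 3.24 in knockout saline and 22.1 ± 4.61 in knockout AngII aortas, against 6.60 ± 4.29 in wild type AngII aortas (SD, n = 5). Arhgap35 had 11.8 ± 0.931, 13.4 ± 2.59 and 14.7 ± 2.25 FPKM in those 3 groups, against 5.94 ± 3.34 in wild type AngII aortas. Snora24 stood at 4.84 ± 1.16 and 6.73 ± 1.17 FPKM in the wild type groups and 1.88 ± 1.00 and 1.56 ± 0.732 in the knockout groups, and Snhg20 at 26.7 ± 11.3 and 34.0 ± 10.7 against 9.45 ± 4.26 and 8.87 ± 2.44. Hmbox1, a homeobox gene, stood at 2.50 ± 1.20 and 1.29 ± 0.315 FPKM in the wild type groups and 5.05 ± 0.516 and 3.77 ± 1.93 in the knockout groups.

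The difference between genotypes seen under AngII may not need AngII. In the saline libraries, which did not choose the genes, 262 of the 275 (95.3%) had the same sign, where 66.9% of all 15010 genes did, 119 of the 262 with an unadjusted p under 0.05. The signed mean of the 275 was 0.17 ± 0.14 in knockout and -0.17 ± 0.06 in wild type aortas (SD, n = 5, exact permutation p = 0.00794, the smallest possible). Over all 15010 genes the genotype differences under saline and AngII had a Pearson r of 0.44 and a Spearman correlation of 0.42. The slope on transcript length differed between genotypes under AngII, less clearly under saline (exact permutation p = 0.0159 and 0.0873), and a length bias was not excluded as a source of this agreement.

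The mitochondrial gene mt-Nd5 was near 0 in 3 libraries, wild type saline replicate 2 (0.654 FPKM), knockout saline replicate 3 (3.83) and knockout AngII replicate 4 (3.93), and between 1035 and 5384 FPKM in the other 17. Assignment of its reads to an unannotated model could leave such a gap. The best matching model stood at 6.92, 2.05 and 5.03 FPKM there, the lowest of these 2.19 times the highest other library (0.925). That is far below the 1035 FPKM or more missing from mt-Nd5, which argues against a model found mainly in these 3 libraries. The test sought only models far higher there than elsewhere. Assignment to a model abundant in every library, or to another annotated transcript, was not tested.

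Chance similarity of the AngII responses was not excluded, since 642 of 1000 shuffles gave a correlation across genes as high as -0.06, with a highest of 0.60.

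For a count of 0 genes the splits decide nothing, since each of the 100 gives at least 0. For AngII against saline the highest other count was 2 in wild type and 3277 in knockout aortas, and for the interaction it was 2734, and the last 2 of these point to a structure of the samples other than treatment. Between genotypes under saline 4 of 100 splits, the real one included, gave at least 2 genes. That share is small, but the splits were chosen after the count had been seen. Moreover, 1 of the other splits called 3747 genes, which again points to such a structure. The count became 1 when any of 7 of the 10 libraries was left out, so chance is not excluded. Chance cannot be excluded for the counts of lists, since as many as the real 9, 13, 11 and 7 were called in 50, 55, 60 and 88 of 100 splits, for AngII in wild type, AngII in knockout, genotype under saline and genotype under AngII. The highest other counts were 18, 20, 21 and 19.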
